A study of Mus musculus with 18 samples.

How the data were processed

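Epididymal and inguinal white fat of C57BL/6 mice was measured by RNA sequencing of 18 samples in 6 groups of 3. Per the labels, control mice lived under 12 h of light and 12 h of dark, and shiftwork mice spent 4 days of each week on that cycle and 3 days on the reversed cycle, for 24 weeks. ZT3 and ZT12 are the hours after lights-on in the regular cycle. The labels name Trizol and column purification of RNA with DNase treatment, an mRNA library kit, and single reads of 51 cycles on an Illumina HiSeq. The submitters' processing notes name STAR, HTSeq, DESeq2, limma and edgeR with the mouse builds mm10 and GRCm38, without versions or roles. The notes do not state the strand used for counting, so reads from antisense transcripts and from overlapping genes cannot be told apart, and reads shared by paralogs may be assigned to either gene.

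For eWAT the authors gave whole-number read counts (counts) for 24091 gene symbols, and all lines carried a symbol (0 without). The authors also gave log2 FPKM values for the same genes and libraries, with a floor of -3.32 for genes without reads. The deposited iWAT table named as read counts holds normalized signal instead: its values are not whole numbers, and each is a whole multiple of a single step per library, as left by division with a size factor. Whole reads were recovered by dividing by that step, which gave whole numbers for 100 percent of 310956 values (largest deviation 1.63e-09). The authors also gave RPKM for iWAT, per the file headers, together with their own comparison of the 2 iWAT groups as log2 fold change and p-value per gene, for which the tool is not stated. The iWAT table holds 51826 Ensembl identifiers, of which 51643 had a symbol of their own, and 23410 symbols were shared with the eWAT table. Gene positions were taken from the eWAT table and belong to the build named in the submitters' processing notes. Apart from the clock scores of control libraries, set side by side at the end, the values of the 2 tables were compared only as differences within each.

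Assigned reads per library ran from 20352008 to 72276733 in eWAT and from 28544338 to 55639501 in iWAT. A gene with 3 reads corresponds to 0.0415 to 0.147 CPM in eWAT and 0.0539 to 0.105 CPM in iWAT, and such floors cover counting error only. No library was a copy of another by chi-square per gene on the genes shared by both tables, where 2 draws from the same library would give about 1 (smallest value 19.2 over 18 pairs within groups and 21.9 over 135 pairs between groups).

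Comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. eWAT counts were fitted with edgeR 4.0.16 in R 4.3.3, with all 12 libraries and 4 groups in the quasi-likelihood model (robust), TMM scaling and filterByExpr (minimum count 10, minimum total 15), which kept 15141 genes. Contrasts were shiftwork against control at ZT3, at ZT12 and averaged, ZT12 against ZT3 in each schedule, and the interaction of schedule and time. The same edgeR test had been planned for iWAT and for the difference between depots. Because the deposited iWAT values were not counts, limma 3.58.1 (trend, robust) on log2(value + 1) was used there in its place. It tested 16159 genes for iWAT and 15527 genes for the depot difference, which fitted 18 libraries. The planned edgeR test could be run on the recovered reads and was kept as an alternative, with 0 and 1 genes called. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. SE of edgeR fold changes was taken as the size of the fold change over the square root of its F value.

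A set of 39 gene lists with 619 genes was fixed beforehand for clock, metabolic, stress, immune and cell type markers, including epididymis and testis, skeletal muscle, mitochondrially encoded and nuclear-retained RNA. Of these, 37 had at least 5 tested genes in each comparison. Lists were tested with camera of limma on logCPM (prior count 2) with a preset correlation between genes of 0.01, with p-values adjusted over lists within a comparison. Counts of members past the test are given over all genes and adjusted over the list alone. Lists were also tested with an estimated correlation, with fry, and with a replicate block. Lists of markers for vas deferens, caput epididymis, spermatids, hepatocytes, intestine and lymph node stroma were added after seeing the data and used only as levels per library. The lymph node stroma list includes Ltb, which lymphocytes also express, so its sum is not separate from lymphocyte levels.

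The genes named in the text follow a fixed rule. It takes every gene of the 2 clock lists. It takes the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05, an average logCPM of at least 1 and no overlap between replicates of the 2 groups (not asked of the interaction or the depot difference), leaving out predicted genes, Riken clones and antibody gene segments. It takes up to 4 members with the smallest p of each list called by camera or with 2 or more members past the test. Genes named outside the rule are marked as such, and markers of other tissues were chosen after seeing the data.

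The fits were tested on simulated negative binomial counts with the library sizes of the data, in which 50 genes per fold were shifted. Each gene was drawn independently, with a single mean and a single spread estimated from the data and used for all groups. The simulation thus held no groups of unequal spread and no transcripts of other tissues, so its rates may not hold for these libraries. In each run 1 to 5 unchanged genes were called. Recovery at folds of 2, 4 and 8 was 24, 72 and 88 percent for shiftwork at ZT3, 22, 60 and 82 percent for time of day in control, 4, 34 and 62 percent for the interaction, 0, 20 and 76 percent for iWAT and 4, 44 and 58 percent for the depot difference. At a fold of 1.5 it was 0 to 14 percent in any comparison.

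Sample numbers were checked as possible pairs by correlating, across genes, the deviations of same-numbered samples from their group means. Of 21 same-numbered pairs 6 had r above 0.1 (range -0.437 to 0.31). At eWAT ZT12 all 3 pairs of control and shiftwork samples did (0.31, 0.132 and 0.203), so the numbers were also fitted as pairs there, and the blocked fit called 0 genes. The labels do not say that the numbers mark pairs. The sample descriptions carry further numbers. Those of all 3 iWAT ZT3 control samples recur, in the same order, in eWAT ZT12 control, and 1 number of the iWAT ZT3 shiftwork samples recurs in eWAT ZT12 shiftwork. Whether these mark animals is not stated, and they were not used. If they do, the time given for 1 of the tissues is in doubt, and iWAT results given for ZT3 and the depot difference, read as a difference at 1 time, would change meaning.

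Alternatives planned beforehand were RLE size factors, no gene filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, limma on the deposited log2 FPKM or on log2(RPKM + 1) and log2(RPKM + 0.1), and, in eWAT, only the 2 groups compared. Added after seeing the data were fits without libraries that held transcripts of other tissues (ZT3 control replicates 1 and 3 and ZT3 shiftwork replicate 3 of eWAT, and control replicates 1 and 2 and shiftwork replicate 1 of iWAT), sample quality weights, a fit of the 2 ZT12 groups with a block, and edgeR with TMM on recovered iWAT reads. The fits with libraries left out still held transcripts of other tissues. Kept were eWAT ZT12 shiftwork replicate 2 (intestine markers, 832 CPM) and iWAT shiftwork replicate 3 (hepatocyte markers, 163 CPM). Also kept was eWAT ZT3 control replicate 2 (spermatid markers, 43.3 CPM). Overlaps used an unadjusted p under 0.01 because too few genes passed the adjusted threshold, and Fisher's exact test, one-sided. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Samples were regrouped in 10 splits of 3 against 3, or 100 where groups were stratified.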

Results

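White adipose tissue of C57BL/6 mice was profiled by RNA sequencing after 24 weeks of a regular or a weekly rotating light schedule. Epididymal fat (eWAT, a visceral depot) was taken at ZT3 and ZT12, and inguinal fat (iWAT, a subcutaneous depot) at ZT3, with n = 3 libraries in each of 6 groups. The 12 eWAT libraries held 20352008 to 72276733 assigned reads, and ZT3 control replicate 1 was the deepest (next 22513786). The 6 iWAT libraries held 28544338 to 55639501 reads, with control replicate 1 the deepest. Fold changes are given on the log2 scale with the standard error (SE), and levels as CPM (counts scaled to library size) with the standard deviation (SD). The p-values of single genes measure spread between samples, and the labels do not say whether the samples are separate animals. Camera p-values with the preset correlation compare the genes of a list with the other genes under an assumed correlation. They do not directly measure spread between samples, and with an estimated correlation no list was called in any comparison.

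Several libraries carried transcripts of tissues other than fat. Akr1b7, an aldo-keto reductase abundant in the vas deferens, stood at 9039, 8.47 and 9325 CPM in eWAT ZT3 control replicates 1 to 3. The summed level of 10 vas deferens markers was 12800, 23.4 and 13500 CPM in the same libraries and 7.05 to 14 CPM in the other eWAT libraries except ZT3 shiftwork replicate 3, at 124 CPM. Markers of spermatids, such as the protamine Prm2 (1232 CPM), summed to 6310 CPM in ZT3 shiftwork replicate 3. They summed to 43.3 CPM in ZT3 control replicate 2, with 10 of 13 above 1 CPM, and to 2.23 and 4.47 CPM in ZT3 shiftwork replicates 1 and 2. Fits below that leave out 3 ZT3 libraries keep ZT3 control replicate 2, so they are not free of germ cell transcripts. Intestine markers summed to 832 CPM in ZT12 shiftwork replicate 2. In iWAT, Cd79a, a chain of the B cell receptor, stood at 118, 245 and 2.29 CPM in control replicates 1 to 3 and at 2.68, 5.49 and 0.316 CPM in the shiftwork libraries. The skeletal muscle genes Ckm and Acta1 stood at 9396 and 10820 CPM in iWAT shiftwork replicate 1, against 125 and 125 CPM in replicate 2.

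**Figure D1:**
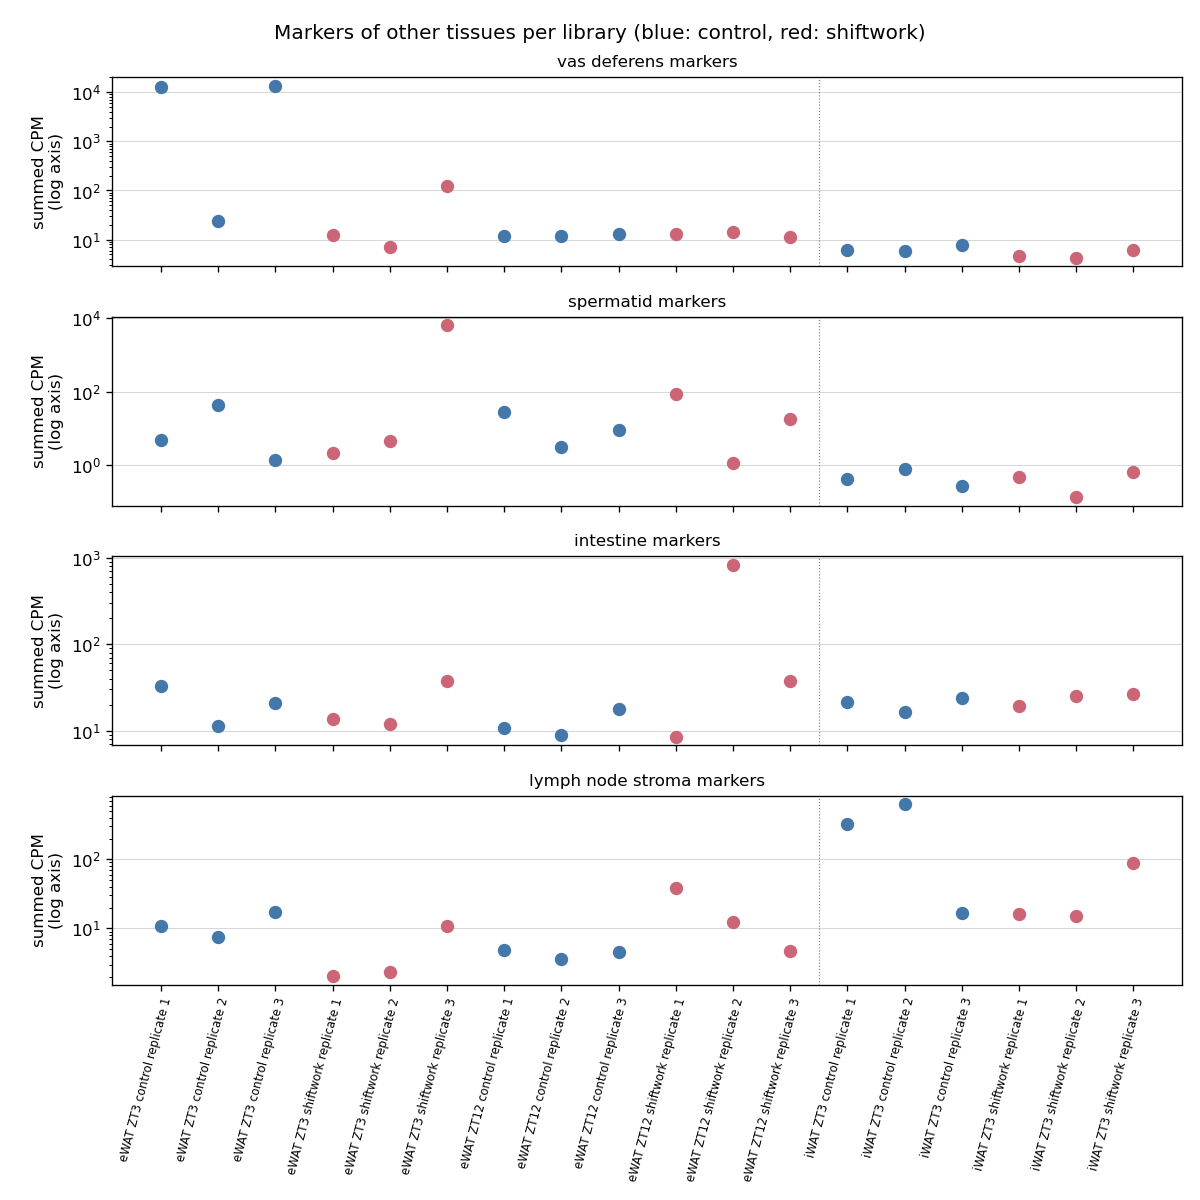
Summed level of markers of other tissues in each library (CPM, log axis); points are single libraries, blue for control and red for shiftwork, and the dotted line parts eWAT from iWAT. The vas deferens markers reached 12800 and 13500 CPM in ZT3 control replicates 1 and 3.

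In eWAT of control mice, genes of the circadian clock differed between ZT3 and ZT12. Arntl, which encodes the clock activator BMAL1, fell by 2.67 ± 0.46 (SE, n = 3 per group, adjusted p = 0.0212, edgeR), from 32.0 ± 17.7 to 5.01 ± 0.519 CPM (SD). Its partner Clock fell by 0.81 ± 0.18 (adjusted p = 0.0414), and the repressor Per2 rose by 1.45 ± 0.30 (adjusted p = 0.0329), from 31.7 ± 11.7 to 86.7 ± 11 CPM. Npas2, a paralog of Clock, differed by -3.96 ± 0.97 (adjusted p = 0.0533). Tef, a clock output factor, differed by 1.03 ± 0.28 (adjusted p = 0.067) and Nr1d1, which encodes the repressor REV-ERB alpha, by -1.12 ± 0.34 (adjusted p = 0.0918). The list of the positive arm of the clock holds Arntl, Clock and Npas2 and, as genes that peak near them, Nfil3 and Cry1, which encode repressors. All 5 were lower at ZT12, 2 of them past the test over all genes and 3 when adjusted over the list alone (limma camera, adjusted p = 0.00211, and adjusted p = 0.314 with an estimated correlation). Of 14 repressor and output genes, 10 were higher, 1 of them past the test over all genes (limma camera, adjusted p = 0.0443, and adjusted p = 0.637 with an estimated correlation).

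**Figure D2:**
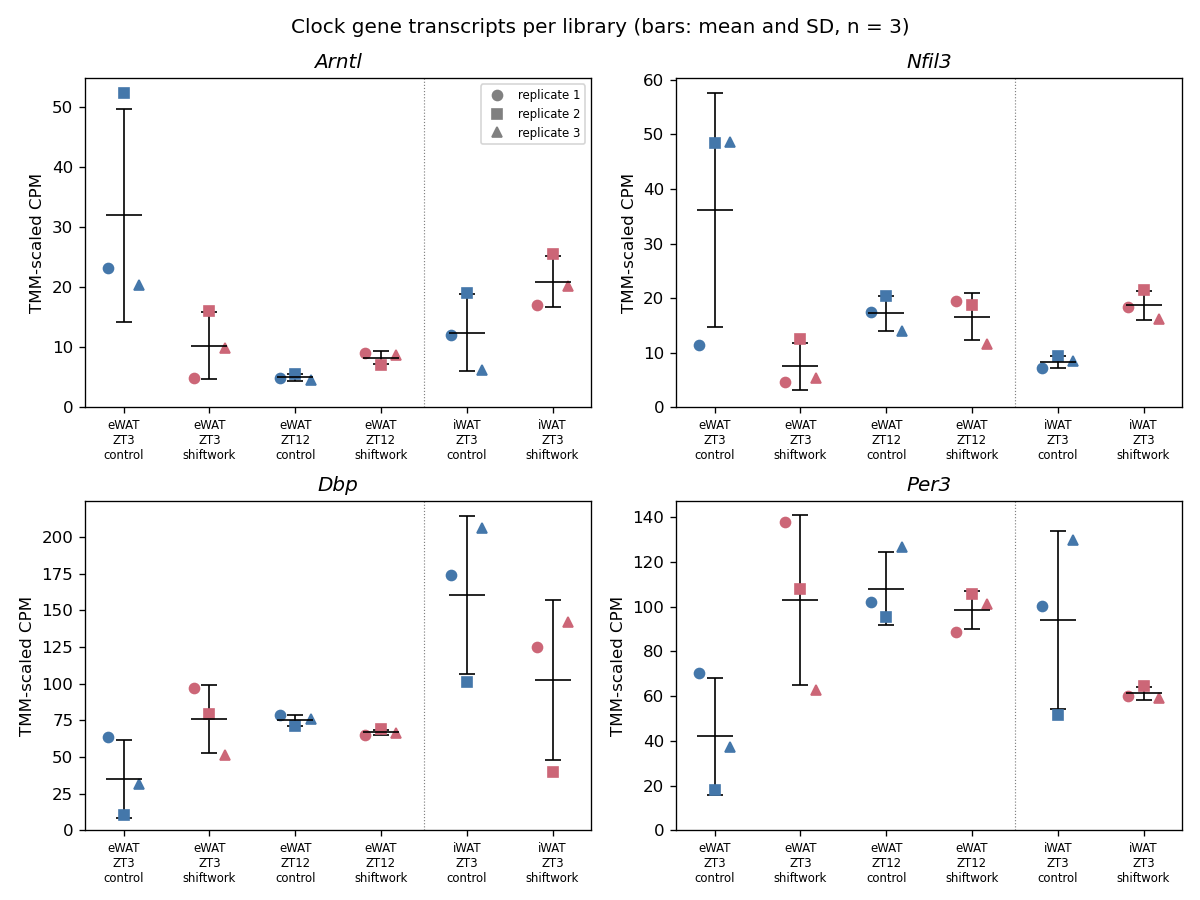
Levels of Arntl, Nfil3, Dbp and Per3 in the 6 groups (TMM-scaled CPM); points are single libraries, blue for control and red for shiftwork, and bars give the mean and SD of n = 3. Arntl stood at 32.0 ± 17.7 CPM in ZT3 control and 5.01 ± 0.519 CPM in ZT12 control eWAT.

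Antiviral and antigen presentation genes were higher at ZT12 in the same libraries. All 20 interferon response genes were higher, and 10 rose past the test over all genes (16 when adjusted over the list alone). Among them were Stat2 by 0.84 ± 0.14 (adjusted p = 0.0195) and the oligoadenylate synthetase Oas2 by 1.41 ± 0.24 (adjusted p = 0.0212). Stat2 went from 39.3 ± 2.12 to 70.4 ± 11.2 CPM. The list had a camera adjusted p of 2.89e-12 (limma, and adjusted p = 0.314 with an estimated correlation). H2-Aa rose by 1.26 ± 0.205 (227 ± 6.08 to 544 ± 28.0 CPM) and H2-Eb1 by 1.23 ± 0.20. Of 7 such MHC class II genes, which present antigen to helper T cells, 6 rose, or 7 when adjusted over the list alone (limma camera, adjusted p = 3.53e-08, and adjusted p = 0.314 with an estimated correlation). The macrophage genes Cd14 (1.26 ± 0.25), Csf1r, the CSF1 receptor (1.28 ± 0.27), and Ms4a7 (1.52 ± 0.33) rose. Of 21 macrophage genes these 3 passed over all genes and 16 when adjusted over the list alone, with a median of 1.28 (limma camera, adjusted p = 5.75e-08, and adjusted p = 0.587 with an estimated correlation). Lysosome and autophagy genes also had a median above 0 (0.56), and the protease gene Ctsk and the lysosomal regulator Tfeb rose by 1.36 ± 0.26 and 0.58 ± 0.13, 2 of 3 that passed the test (limma camera, adjusted p = 6.18e-07, and adjusted p = 0.314 with an estimated correlation).

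Metabolic lists leaned the other way at ZT12. Of 36 oxidative phosphorylation genes 35 were lower and none passed the test (median -0.27; limma camera, adjusted p = 0.000472, and adjusted p = 0.688 with an estimated correlation). Of 24 cholesterol synthesis genes 21 were lower, and the sterol reductase gene Tm7sf2 fell by 1.17 ± 0.24 (limma camera, adjusted p = 0.000507, and adjusted p = 0.637 with an estimated correlation). The lipogenesis list, with Fads1 at -1.32 ± 0.385 (adjusted p = 0.0819), had a median of -0.55 (limma camera, adjusted p = 0.046, and adjusted p = 0.699 with an estimated correlation). Of 28 extracellular matrix genes 26 were higher, and Col12a1 and Sparc rose by 1.90 ± 0.37 and 1.03 ± 0.23 (limma camera, adjusted p = 0.00128, and adjusted p = 0.637 with an estimated correlation). All 25 cell cycle genes were higher with none past the test (limma camera, adjusted p = 0.00165, and adjusted p = 0.688 with an estimated correlation).

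**Figure D3:**
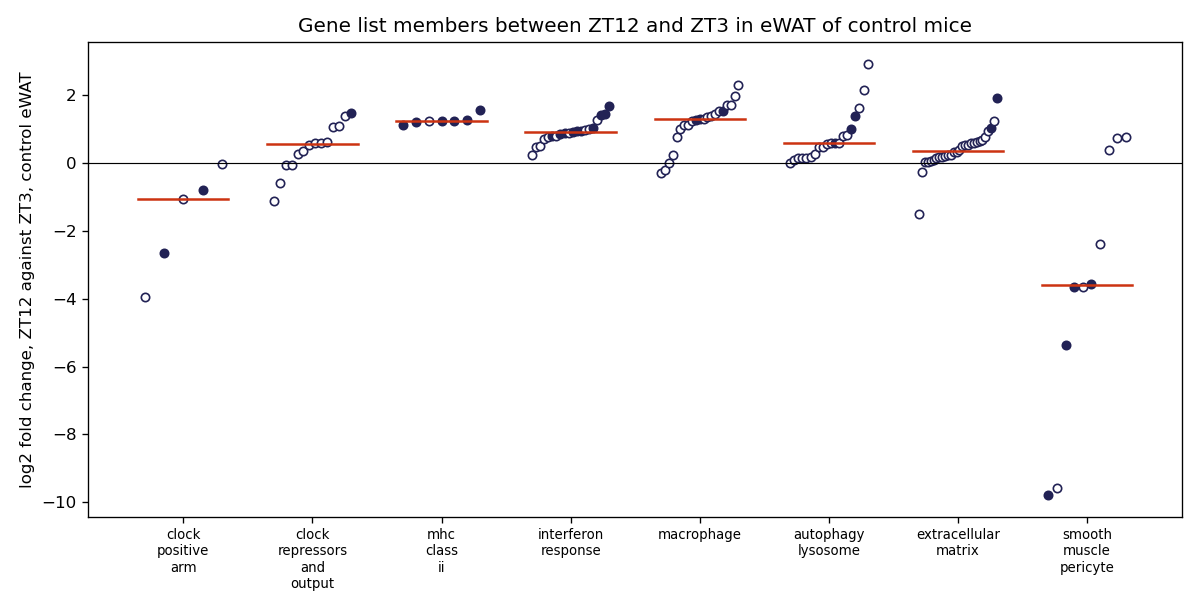
Log2 fold change of ZT12 against ZT3 in control eWAT for the members of gene lists; each point is a gene, filled where it passed the test, lines are medians, and positive values are higher at ZT12. The interferon response list had a median of 0.89 and the MHC class II list a median of 1.23.

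The largest rises between ZT3 and ZT12 were those of Gpr50, an orphan receptor related to the melatonin receptors (5.96 ± 1.09), Ugt3a2 (3.37 ± 0.48), Car12, a carbonic anhydrase (3.30 ± 0.67), the imprinted gene Peg3 (2.89 ± 0.45), Pmepa1 (2.64 ± 0.35) and the secretory kinase gene Fam20c (2.58 ± 0.31). Fam20c (chromosome 5, 138755081 to 138810063, plus strand) went from 41.7 ± 6.50 to 249 ± 50.9 CPM. The largest falls were those of Crisp1 (-11.48 ± 2.03), Akr1b7 (-11.44 ± 2.07), Ptgs2 (-10.00 ± 1.79), and the smooth muscle gene Cnn1 (-9.78 ± 2.07). These moved with the vas deferens markers, which were chosen after seeing the data, so that is no separate evidence of their source. Crisp1, a secreted protein of the male tract, stood at 2333, 2.82 and 2664 CPM in ZT3 control replicates 1 to 3, and Ptgs2, the inducible cyclooxygenase, at 1567, 5.89 and 2200 CPM. Myh11 fell by 5.35 ± 1.21 and stood at 5070, 79.0 and 3217 CPM in those libraries. Of 10 smooth muscle genes 4 fell (limma camera, adjusted p = 0.039, and adjusted p = 0.688 with an estimated correlation). Of 7 epithelial genes 1, Krt10, fell by 1.18 ± 0.28 (limma camera, adjusted p = 0.000381, and adjusted p = 0.314 with an estimated correlation). B and plasma cell genes had a median of -2.30 with none past the test over all genes, and 11 of 12 were lower when adjusted over the list alone (limma camera, adjusted p = 3.53e-08, and adjusted p = 0.444 with an estimated correlation). Their summed level was 84.9, 94.5 and 298 CPM in the ZT3 control libraries. Lymph node stroma markers fell with them, from 10.9, 7.55 and 17.3 CPM at ZT3 to 4.94, 3.59 and 4.51 CPM at ZT12. Immediate early genes split, with Jun (0.84 ± 0.12) and Klf2 (0.79 ± 0.18) rising and Egr1 (-3.56 ± 0.75) and Ier2 falling (-1.51 ± 0.36). The list was not called (limma camera, adjusted p = 0.158), and Egr1 stood at 33.9, 454 and 409 CPM in ZT3 control replicates 1 to 3.

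For eWAT time of day in control mice, 559 of 15141 genes differed, 443 higher and 116 lower at ZT12 (edgeR, 3393 with unadjusted p under 0.05). DESeq2 called 2168 genes, 1170 higher and 998 lower, all 559 among them. Without gene filtering 320 were called, 274 higher and 46 lower. With the 3 ZT3 libraries that carried male tract or germ cell transcripts left out, a choice made after seeing the data that leaves replicate 2 as the sole ZT3 control, 619 genes were called, 268 higher and 351 lower, of which 185 were shared. In that fit the matrix and epithelial lists lost their calls (limma camera, adjusted p = 0.168 and 0.164) and the smooth muscle list pointed up (adjusted p = 0.438). Leaving out 1 library moved the count by more than 1.5 times for 10 of 12 libraries: ZT3 control replicate 1 (173), 2 (1208) and 3 (3), ZT3 shiftwork replicate 1 (276) and 3 (2744), ZT12 control replicate 1 (1), 2 (4) and 3 (121), and ZT12 shiftwork replicate 2 (144) and 3 (155).

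At ZT3, eWAT of shiftwork mice held lower levels of positive-arm clock genes and higher levels of most clock repressors and outputs than eWAT of controls, though no single gene passed the test over all genes. Arntl stood at 10.2 ± 5.58 CPM in shiftwork and 32.0 ± 17.7 CPM in control mice (-1.64 ± 0.45, n = 3 per group, adjusted p = 0.198, edgeR). Nfil3, a repressor of D-box genes, stood at 7.51 ± 4.32 and 36.2 ± 21.4 CPM (-2.27 ± 0.55, adjusted p = 0.194). Clock differed by -0.60 ± 0.18, while the output factor Tef differed by 0.98 ± 0.28 and the period gene Per3 by 1.29 ± 0.42. Of 5 positive-arm genes 4 were lower, 3 of them past the test when adjusted over the list alone (limma camera, adjusted p = 0.00136, and adjusted p = 0.347 with an estimated correlation). Of 14 repressor and output genes 13 were higher (limma camera, adjusted p = 0.000921, and adjusted p = 0.347 with an estimated correlation). A clock score per library, the mean log2(CPM + 1) of the positive arm minus that of the repressors and outputs, was -2.04 ± 0.420 in shiftwork and -0.366 ± 0.986 in control mice. The difference was -1.67 ± 0.445 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The SE of score differences in eWAT pools the spread of all 4 eWAT groups, whose SD ran from 0.0767 to 0.986.

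Sterol and fatty acid synthesis genes were lower in shiftwork eWAT at ZT3. Of 24 cholesterol synthesis genes 23 were lower, 8 of them past the test when adjusted over the list alone (limma camera, adjusted p = 3.29e-09, and adjusted p = 0.347 with an estimated correlation). Tm7sf2 stood at 6.64 ± 1.4 against 17.2 ± 3.80 CPM (-1.37 ± 0.245, adjusted p = 0.17, edgeR), and Stard4, a carrier of cholesterol between membranes, differed by -0.91 ± 0.23. Elovl6, a fatty acid elongase, and Fads1, a desaturase, stood at -1.50 ± 0.55 and -1.27 ± 0.385. In all 19 of 20 lipogenesis genes were lower (limma camera, adjusted p = 9.15e-05, and adjusted p = 0.611 with an estimated correlation). Egr2 and Egr1 stood at -3.15 ± 0.625 and -3.23 ± 0.74, and Jun at 0.52 ± 0.12. Of 22 such immediate early genes 20 were lower (limma camera, adjusted p = 4.96e-06, and adjusted p = 0.347 with an estimated correlation). Heat shock genes such as Hspa1b (-2.02 ± 0.45) and glucocorticoid-responsive genes such as Cdkn1a (-1.72 ± 0.47) also lay lower (limma camera, adjusted p = 0.012 and 0.0265, and adjusted p = 0.347 and 0.686 with an estimated correlation).

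Immune and stromal lists differed at ZT3 as well. All 7 MHC class II genes were higher in shiftwork eWAT, H2-Aa by 0.57 ± 0.20 (limma camera, adjusted p = 0.00169, and adjusted p = 0.611 with an estimated correlation). So were 18 of 20 interferon response genes, Irf7 by 0.50 ± 0.14 (limma camera, adjusted p = 0.00823, and adjusted p = 0.686 with an estimated correlation). Without the 3 libraries with male tract or germ cell transcripts the MHC class II list had an adjusted p of 0.284. Of 25 cell cycle genes 23 were higher (median 1.17; limma camera, adjusted p = 0.012, and adjusted p = 0.775 with an estimated correlation). Without those libraries the adjusted p was 0.494, with ZT3 control replicate 2 the sole control left. All 12 B and plasma cell genes were lower, with Jchain, the joining chain of secreted antibodies, at -3.45 ± 0.64 (limma camera, adjusted p = 4.05e-09, and adjusted p = 0.347 with an estimated correlation). Lymph node stroma markers summed to 10.9, 7.55 and 17.3 CPM in the ZT3 control libraries and 2.04, 2.33 and 11 CPM in ZT3 shiftwork. Smooth muscle genes had a median of -3.50, with Myh11 at -4.85 ± 1.18 (limma camera, adjusted p = 0.00169, and adjusted p = 0.611 with an estimated correlation). Myh11 was high in the 2 control libraries that held vas deferens markers. Without the 3 libraries the smooth muscle list pointed up (adjusted p = 0.887). All 7 epithelial genes were lower (limma camera, adjusted p = 0.00021, and adjusted p = 0.347 with an estimated correlation), and adjusted p was 0.0177 without the 3 libraries. Mesothelial and Schwann cell lists had medians of -0.47 and -0.76 (limma camera, adjusted p = 0.0272 and 0.0476, and adjusted p = 0.686 and 0.397 with an estimated correlation). Both lost their calls without the 3 libraries (adjusted p = 0.333 and 0.808).

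No gene of 15141 passed the edgeR test for eWAT shiftwork at ZT3 (2847 with unadjusted p under 0.05), whereas DESeq2 called 629, 258 higher and 371 lower. Of the 371 lower DESeq2 calls, 167 were more than 2-fold higher in ZT3 control replicates 1 and 3, each, than in replicate 2. With 3 libraries left out after seeing the data, 1 ZT3 control library (replicate 2) remained, assumed to vary like the other groups. In that fit edgeR called 9 genes, among them Dbp (3.05 ± 0.161, adjusted p = 0.000611), a clock output factor, with Per3 and Tef also higher and Arc, Egr1 and Zfp36 lower. These 9 were named after their values were seen. Leaving out ZT3 control replicate 1, replicate 2 or ZT3 shiftwork replicate 3 gave 3, 403 and 1 genes. Without replicate 2, 356 genes were called lower. Of these 285 (80.1 percent) were more than 2-fold higher in the 2 control libraries with vas deferens transcripts, each, than in replicate 2. Of all tested genes 9.4 percent were. Replicates 1 and 3 were the only ZT3 controls of that fit and picked those genes, so the share partly follows from the choice.

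At ZT12, shiftwork eWAT held lower levels of interferon response genes and higher levels of B cell, mast cell and ribosomal protein genes than control eWAT, with no single gene past the test. Of 20 interferon response genes 19 were lower (median -0.42; limma camera, adjusted p = 1.95e-15, and adjusted p = 0.297 with an estimated correlation). Oas2 stood at 19.7 ± 4.98 CPM in shiftwork and 33.3 ± 2.15 CPM in control mice (-0.76 ± 0.24, n = 3 per group, adjusted p = 1, edgeR), and Stat2 at 50.1 ± 3.24 and 70.4 ± 11.2 CPM. All 7 MHC class II genes lay lower too (median -0.23; limma camera, adjusted p = 0.00858, and adjusted p = 0.683 with an estimated correlation). Of 12 B and plasma cell genes 11 were higher, with the B cell surface gene Ms4a1 at 2.21 ± 0.79 (limma camera, adjusted p = 2.76e-09, and adjusted p = 0.48 with an estimated correlation). The mast cell chymase gene Cma1 stood at 7.98 ± 2.59 against 3.27 ± 1.88 CPM (list, limma camera, adjusted p = 6.29e-05, and adjusted p = 0.48 with an estimated correlation). Of 29 ribosomal protein genes 28 were higher, by a median of 0.18 (limma camera, adjusted p = 1.92e-07, and adjusted p = 0.557 with an estimated correlation).

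Glucocorticoid-responsive genes were lower in 14 of 15 cases at ZT12, with the phosphatase gene Dusp1 at -0.59 ± 0.21 (limma camera, adjusted p = 0.000914, and adjusted p = 0.557 with an estimated correlation). All 25 cell cycle genes were higher (limma camera, adjusted p = 0.000401, and adjusted p = 0.769 with an estimated correlation). Higher too were all 5 lymphatic endothelial genes, with the lymphatic regulator Prox1 at 3.24 ± 1.34 (limma camera, adjusted p = 4.38e-06, and adjusted p = 0.297 with an estimated correlation). Markers of lymph node stroma summed to 39, 12.3 and 4.78 CPM in the ZT12 shiftwork libraries and 3.59 to 4.94 CPM in the controls, beside the higher lymphatic and B cell genes. Extracellular matrix, fibroblast and mesothelial lists lay higher, with elastin (Eln) at 0.71 ± 0.22 (limma camera, adjusted p = 0.00504, 0.00675 and 0.0113, and adjusted p = 0.683, 0.48 and 0.698 with an estimated correlation). Without the 3 ZT3 libraries the matrix and mesothelial lists lost their calls (adjusted p = 0.112 and 0.131). With the replicate block the T and NK cell list, lower in 10 of 14 genes, was called as well (limma camera, adjusted p = 0.0293, against 0.122 without the block, and adjusted p = 0.855 with an estimated correlation). The clock lists were not called at ZT12, where Per1 and Per2 stood at -0.57 ± 0.27 and -0.61 ± 0.29 and Arntl at 0.73 ± 0.44. No gene of 15141 passed the edgeR test (355 with unadjusted p under 0.05), and a replicate block, which fitted the sample numbers as pairs, also gave 0. DESeq2 called 7 genes, all higher, among them Corin (20.67 ± 2.6), Cyp3a13, Cytl1, Cdh17 and Krt20, named after their values were seen. Cdh17 and Krt20 are genes of the intestinal lining, whose markers summed to 832 CPM in ZT12 shiftwork replicate 2. The source of the other calls was not tested.

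Averaged over ZT3 and ZT12, shiftwork eWAT had lower sterol synthesis, heat shock and glucocorticoid-responsive genes and higher cell cycle genes, again with no single gene past the test. Of 24 cholesterol synthesis genes 23 were lower, Stard4 by -0.49 ± 0.165 (n = 6 per schedule, adjusted p = 0.574, edgeR, and limma camera, adjusted p = 2.06e-06, and adjusted p = 0.645 with an estimated correlation). All 20 lipogenesis genes were lower (limma camera, adjusted p = 0.000513, and adjusted p = 0.787 with an estimated correlation). At ZT12 alone, 15 of 24 cholesterol synthesis genes and 12 of 20 lipogenesis genes were higher (medians 0.09 and 0.06, limma camera, adjusted p = 0.177 and 0.824), so the averaged values followed ZT3. Bag3, a co-chaperone, stood at -0.48 ± 0.14 and Dusp1 at -0.63 ± 0.15 (heat shock and glucocorticoid lists, limma camera, adjusted p = 0.001 and 0.000138, and adjusted p = 0.184 and 0.645 with an estimated correlation). Egr2 stood at -1.60 ± 0.42 and Ube2c at 0.84 ± 0.20. Of 22 immediate early genes 20 were lower, and all 25 cell cycle genes were higher (limma camera, adjusted p = 5.34e-05 for each, and adjusted p = 0.645 and 0.787 with an estimated correlation). The chemokine genes Ccl2 and Ccl7 stood at -1.45 ± 0.48 and -1.33 ± 0.46 (inflammatory list, limma camera, adjusted p = 0.0247, and adjusted p = 0.787 with an estimated correlation). The positive arm of the clock was lower in all 5 members and the repressors and outputs higher in 12 of 14 (limma camera, adjusted p = 0.0144 and 0.0159, and adjusted p = 0.645 for each with an estimated correlation). These and the immediate early genes also followed ZT3, since at ZT12 alone 3 of 5 positive-arm genes and 13 of 22 immediate early genes were higher and 10 of 14 repressors and outputs lower (limma camera, adjusted p = 0.307, 0.806 and 0.321).

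For B and plasma cell genes the averaged median was above 0 (0.05) while the mean (-0.16) and the camera direction were below it (limma, adjusted p = 0.0355, and adjusted p = 0.787 with an estimated correlation), and Jchain stood at -2.15 ± 0.43. For epithelial genes the mean (0.08) was above 0 and the median (-0.15) and direction below (limma, adjusted p = 0.0149, and adjusted p = 0.645 with an estimated correlation). Fibroblast, matrix and lymphatic lists lay higher, with the progenitor marker Cd34 at 0.45 ± 0.11 (limma camera, adjusted p = 0.0404, 0.0404 and 0.0243, and adjusted p = 0.656, 0.787 and 0.645 with an estimated correlation). B and plasma cell, epithelial and smooth muscle genes went opposite ways, with 0 of 12, 0 of 7 and 3 of 10 higher at ZT3 and 11, 6 and 7 higher at ZT12. T and NK cell and smooth muscle lists lay lower (limma camera, adjusted p = 0.0293 and 0.0446, and adjusted p = 0.787 for each with an estimated correlation). Without the 3 libraries with male tract or germ cell transcripts the smooth muscle list pointed up (adjusted p = 0.00119), and matrix, T and NK cell, lymphatic and epithelial lists lost their calls (adjusted p = 0.105 to 0.417). No gene of 15141 passed the edgeR test (1297 with unadjusted p under 0.05), and DESeq2 called 42. Leaving out ZT3 control replicate 2 gave 88 genes. Leaving out the 3 libraries, with ZT3 control replicate 2 the sole ZT3 control left, gave 4, namely Dbp, Per3, Arc and Zfp36, which were named after their values were seen.

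Between ZT3 and ZT12 in shiftwork eWAT, macrophage, lysosome, MHC class II and matrix genes were higher at ZT12, with no single gene past the test. Of 21 macrophage genes 20 were higher, 11 of them past the test when adjusted over the list alone (limma camera, adjusted p = 1.4e-10, and adjusted p = 0.547 with an estimated correlation). The lysozyme gene Lyz2 stood at 1.48 ± 0.35 (n = 3 per group, adjusted p = 0.28, edgeR) and Cd68 at 1.42 ± 0.41. Inflammatory genes were higher in 20 of 25 cases, with the acute phase gene Saa3 at 2.39 ± 0.59 (limma camera, adjusted p = 9.29e-05, and adjusted p = 0.547 with an estimated correlation). Of 28 matrix genes 27 were higher, with Eln at 0.86 ± 0.22 (limma camera, adjusted p = 6.75e-08, and adjusted p = 0.547 with an estimated correlation). The matrix protease gene Mmp2 stood at 0.68 ± 0.175 (TGF-beta list, limma camera, adjusted p = 0.000228, and adjusted p = 0.547 with an estimated correlation). MHC class II and lysosome lists had medians of 0.43 and 0.33 (limma camera, adjusted p = 0.000108 and 0.000734, and adjusted p = 0.547 for each with an estimated correlation). Of 24 cholesterol synthesis genes 19 were higher, though the squalene synthase gene Fdft1 stood at -1.07 ± 0.25 (limma camera, adjusted p = 0.00502, and adjusted p = 0.748 with an estimated correlation). Interferon, immediate early, cell cycle, neutrophil, mast cell, B cell, fibroblast and ribosomal lists also lay higher (limma camera, adjusted p = 0.000931 to 0.0338, and adjusted p = 0.547 to 0.801 with an estimated correlation). Lymph node stroma markers summed to 2.04, 2.33 and 11 CPM at ZT3 and 39, 12.3 and 4.78 CPM at ZT12 in these libraries.

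The clock lists were not called between times in shiftwork mice, where Arntl stood at 10.2 ± 5.58 CPM at ZT3 and 8.31 ± 1.16 CPM at ZT12 (-0.30 ± 0.44, adjusted p = 0.779, edgeR) and Per2 at 48.8 ± 9.06 and 56.7 ± 20.1 CPM. No gene of 15141 passed the edgeR test (2461 with unadjusted p under 0.05), and DESeq2 called 287. With the 3 ZT3 libraries left out after seeing the data, which leaves 2 shiftwork libraries at ZT3, 75 genes were called. In that fit interferon, cholesterol, lysosome, mast cell, fibroblast and ribosomal lists lost their calls (limma camera, adjusted p = 0.0501 to 0.694).

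For the interaction of shiftwork and time, camera with the preset correlation called 19 of 37 lists. With an estimated correlation and with fry 0 were called, so a different time-of-day difference between schedules was not established. The positive arm of the clock had an interaction above 0 in 4 of 5 genes, Arntl by 2.37 ± 0.625 (n = 3 per group, adjusted p = 0.419, edgeR). The repressors and outputs had a negative one in 12 of 14, Per2 by -1.24 ± 0.41 (both lists, limma camera, adjusted p = 0.00126 and 0.000934, and adjusted p = 0.31 for each with an estimated correlation). Thus the ZT12 against ZT3 difference of Arntl was -2.67 in control and -0.30 in shiftwork mice. Interferon response genes had a negative interaction in 19 of 20 cases, 7 of them past the test when adjusted over the list alone (limma camera, adjusted p = 6.91e-09, and adjusted p = 0.31 with an estimated correlation). So did all 7 MHC class II genes (limma camera, adjusted p = 0.000199, and adjusted p = 0.446 with an estimated correlation). Irf7 stood at -0.75 ± 0.20 and H2-Aa at -0.87 ± 0.29. Of 24 cholesterol synthesis genes 23 had a positive interaction, Tm7sf2 by 1.77 ± 0.34 (adjusted p = 0.372, edgeR, and limma camera, adjusted p = 1.11e-08, and adjusted p = 0.328 with an estimated correlation). The mast cell proteases Cma1 and Tpsb2 stood at 2.79 ± 0.60 and 2.62 ± 0.57 (list, limma camera, adjusted p = 0.00219, and adjusted p = 0.446 with an estimated correlation). All 12 B and plasma cell genes had a positive interaction (limma camera, adjusted p = 2.61e-13, and adjusted p = 0.31 with an estimated correlation). Lymph node stroma markers crossed likewise, with 7.55 to 17.3 CPM in control and 2.04 to 11 CPM in shiftwork at ZT3, and 3.59 to 4.94 and 4.78 to 39 CPM at ZT12.

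Lipogenesis and immediate early genes had positive interactions, with Egr1 at 3.53 ± 0.99 and Jun at -0.88 ± 0.17 (limma camera, adjusted p = 0.000883 and 0.000111, and adjusted p = 0.556 and 0.328 with an estimated correlation). Smooth muscle and epithelial lists had medians of 4.51 and 3.61, with Cnn1 at 11.17 ± 2.47 (limma camera, adjusted p = 0.000871 and 6.55e-05, and adjusted p = 0.446 and 0.31 with an estimated correlation). Epithelial genes summed to 254, 18.6 and 261 CPM in the ZT3 control libraries and 207 CPM in ZT3 shiftwork replicate 3, but without the 3 libraries the list kept its call (limma camera, adjusted p = 0.00536). Mesothelial, Schwann, lymphatic, ribosomal, oxidative phosphorylation, antioxidant and TGF-beta lists also had medians above 0, and the lysosome list below (limma camera, adjusted p = 0.000934 to 0.0342, and adjusted p = 0.31 to 0.885 with an estimated correlation). Without the 3 libraries mast cell, smooth muscle, mesothelial, Schwann, lymphatic, ribosomal, oxidative phosphorylation, antioxidant and lysosome lists lost their calls (limma camera, adjusted p = 0.102 to 0.361). No gene of 15141 passed the edgeR test of the interaction (1535 with unadjusted p under 0.05), and DESeq2 called 189. Leaving out ZT3 control replicate 1, replicate 2 or ZT3 shiftwork replicate 3 gave 1, 186 and 15 genes. Leaving out the 3 libraries, with ZT3 control replicate 2 the sole ZT3 control left, gave 7 genes, among them Dbp, Per3, Tef, Arc and Egr1, named after their values were seen.

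In iWAT at ZT3, shiftwork mice had higher levels of positive-arm clock genes, matrix and stress-responsive genes and lower levels of lymphocyte genes than controls, with no single gene past the test. All 5 positive-arm genes were higher (limma camera, adjusted p = 0.00129, and adjusted p = 0.613 with an estimated correlation). Nfil3 stood at 18.7 ± 2.62 against 8.38 ± 1.12 CPM (1.16 ± 0.21, n = 3 per group, adjusted p = 0.69, limma), Npas2 at 2.29 ± 0.358 against 1.07 ± 0.153 CPM, and Arntl at 20.9 ± 4.27 against 12.5 ± 6.40 CPM. All 28 matrix genes were higher, with the matricellular gene Thbs1 at 2.26 ± 0.35 (limma camera, adjusted p = 5.52e-11, and adjusted p = 0.726 with an estimated correlation). The growth factor gene Ctgf stood at 24.7 ± 4.98 against 9.07 ± 2.25 CPM (TGF-beta list, limma camera, adjusted p = 0.0292, and adjusted p = 0.726 with an estimated correlation). Glucocorticoid-responsive genes were higher in 12 of 15 cases, with the cell cycle inhibitor gene Cdkn1a at 1.33 ± 0.29 (limma camera, adjusted p = 0.000507, and adjusted p = 0.613 with an estimated correlation). Heat shock genes were higher in 14 of 16 cases, with Hspb1 at 1.39 ± 0.34 and the cold-inducible gene Cirbp at -1.05 ± 0.29 (limma camera, adjusted p = 0.00981, and adjusted p = 0.726 with an estimated correlation). Inflammatory genes lay higher, with Ccl2 at 2.39 ± 0.73 (limma camera, adjusted p = 0.00107, and adjusted p = 0.726 with an estimated correlation). Of 20 lipogenesis genes 15 were lower, with Elovl6 at -1.99 ± 0.78 (limma camera, adjusted p = 0.0118, and adjusted p = 0.726 with an estimated correlation).

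Lymphocyte genes stood lower in shiftwork iWAT, by medians of -4.48 for B and plasma cell genes and -2.66 for T and NK cell genes (limma camera, adjusted p = 5.68e-07 and 2.75e-05, and adjusted p = 0.726 for each with an estimated correlation). Ms4a1 stood at 137, 195 and 2.78 CPM in the control libraries and 1.61, 6.38 and 0.281 CPM in the shiftwork libraries, and Cd4 at 71.5, 137 and 4.22 against 3.67, 3.69 and 3.87 CPM. All 7 MHC class II genes were lower (limma camera, adjusted p = 0.0158, and adjusted p = 0.726 with an estimated correlation). Markers of lymph node stroma summed to 321, 626 and 16.5 CPM in the control libraries. With the 3 libraries that held lymphocyte or muscle transcripts left out after seeing the data, 2 shiftwork libraries stand against control replicate 3 alone, assumed to vary like them. In that fit the MHC class II and the T and NK cell lists pointed up (limma camera, adjusted p = 0.0103 and 0.000172). Skeletal muscle genes were higher in 12 of 12 cases, mainly through shiftwork replicate 1, with Myh4, a fast myosin, at 5.11 ± 2.09 (limma camera, adjusted p = 3.97e-06, and adjusted p = 0.726 with an estimated correlation). Of 30 ribosomal protein genes 29 were lower, and the lymphatic list lay lower, with Prox1 at -2.81 ± 1.10 (limma camera, adjusted p = 0.000178 and 0.0292, and adjusted p = 0.726 for each with an estimated correlation). Endothelial, smooth muscle, macrophage, lysosome, endoplasmic reticulum chaperone, fatty acid oxidation, interferon and red cell lists lay higher (limma camera, adjusted p = 0.00107 to 0.0307, and adjusted p = 0.726 to 0.775 with an estimated correlation). Without the 3 libraries the fatty acid oxidation list pointed down (limma camera, adjusted p = 0.00191), and lysosome, red cell, lymphatic and ribosomal lists turned without a call (adjusted p = 0.151 to 0.677). TGF-beta, glucocorticoid, macrophage and B cell lists kept their direction and lost their calls (limma camera, adjusted p = 0.12 to 0.677).

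For iWAT shiftwork at ZT3 no gene of 16159 passed the limma test (1073 with unadjusted p under 0.05). With edgeR on recovered reads 0 were called (1599 unadjusted), and DESeq2 called 445, 138 higher and 307 lower. Leaving out control replicate 3 gave 827 genes, 48 higher and 779 lower. Of these lower genes 746 (95.8 percent) were more than 2-fold higher in control replicates 1 and 2, each, than in replicate 3. Replicates 1 and 2 were the only controls of that fit, so the share partly follows from how the genes were picked. Of the lower DESeq2 calls 264 (86 percent) were, and of 2137 lower calls with sample quality weights 893 (41.8 percent). The share over all tested genes was not computed. The authors' table of this comparison holds 426 genes with an adjusted p under 0.05, 110 higher and 316 lower. Of the DESeq2 calls 321 were among them, all with the same sign, and the authors' fold changes correlated with those of limma at r = 0.955 over 16159 genes, which are not independent replicates. Of the authors' 316 lower genes 291 were more than 2-fold higher in control replicates 1 and 2, each, than in replicate 3.

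The shiftwork difference at ZT3 itself differed between depots for 2 of 15527 genes, both relatively higher in iWAT (limma, 1762 with unadjusted p under 0.05). All numbers of the iWAT control samples recur in eWAT ZT12 control, so if they mark animals, the time of either set is in doubt. Adamts4, a protease of the cartilage proteoglycan aggrecan, stood at 11.9 ± 4.28 against 2.17 ± 0.160 CPM in iWAT and at 1.71 ± 0.302 against 3.93 ± 0.795 CPM in eWAT (difference of 3.58 ± 0.45, n = 3 per group, adjusted p = 0.0137). Phlda1 stood at 24.1 ± 5.54 against 15.1 ± 2.84 CPM in iWAT and at 8.56 ± 0.903 against 28.7 ± 7.47 CPM in eWAT (difference of 2.41 ± 0.35, adjusted p = 0.039). All 5 positive-arm clock genes had a positive difference, Nfil3 by 3.32 ± 0.66 (adjusted p = 0.128) and Arntl by 2.56 ± 0.64 (adjusted p = 0.248), and 4 passed when adjusted over the list alone (limma camera, adjusted p = 0.000242, and adjusted p = 0.251 with an estimated correlation). Of 14 repressors and outputs 12 had a negative difference, Per3 by -1.91 ± 0.58 (limma camera, adjusted p = 0.000462, and adjusted p = 0.459 with an estimated correlation).

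**Figure D4:**
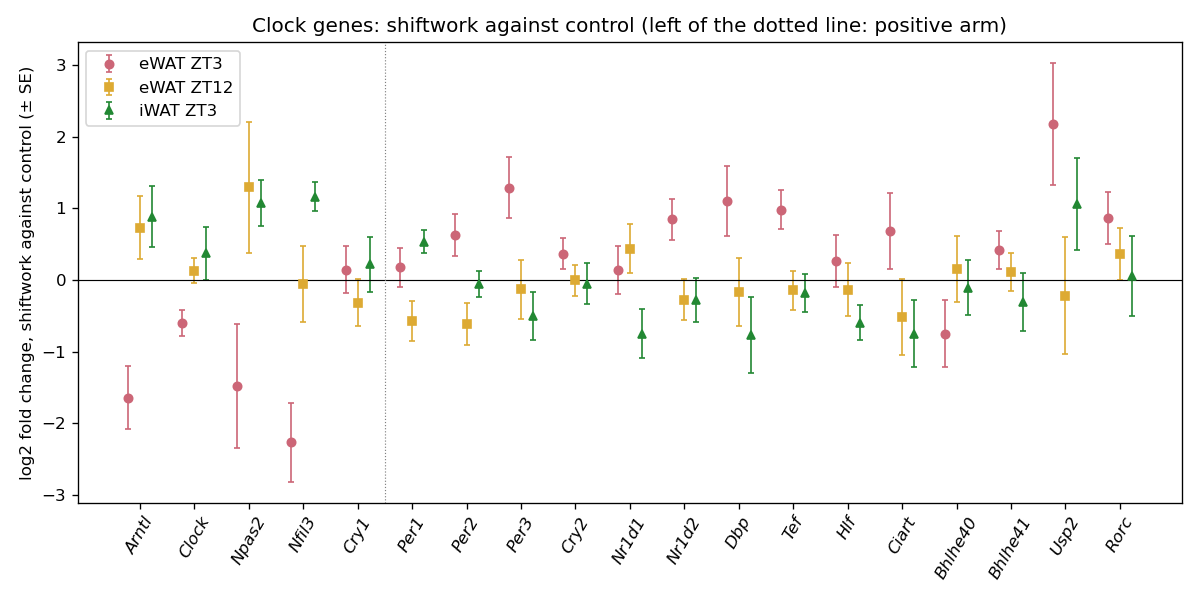
Log2 fold change of shiftwork against control for clock genes in eWAT at ZT3, eWAT at ZT12 and iWAT at ZT3 (bars are SE, n = 3 per group); the positive arm lies left of the dotted line. Arntl stood at -1.64 in eWAT and 0.88 in iWAT at ZT3.

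By camera with the preset correlation, stress-responsive groups also differed between depots. Heat shock genes had a positive difference in 12 of 16 cases, Bag3 by 1.42 ± 0.28 (limma camera, adjusted p = 0.000242, and adjusted p = 0.251 with an estimated correlation). So did 14 of 15 glucocorticoid-responsive genes, Cdkn1a by 2.94 ± 0.61 (limma camera, adjusted p = 0.000242, and adjusted p = 0.459 with an estimated correlation). Endoplasmic reticulum chaperone, immediate early and inflammatory lists differed in the same direction, with the stress factor gene Atf4 at 1.11 ± 0.21, Egr2 at 3.35 ± 0.765 and Ccl2 at 4.38 ± 1.10 (limma camera, adjusted p = 0.000572, 5.08e-05 and 0.00061, and adjusted p = 0.459 for each with an estimated correlation). Matrix, cholesterol synthesis and TGF-beta lists had medians of 0.84, 0.89 and 0.52 (limma camera, adjusted p = 1.31e-06, 1.74e-05 and 0.0231, and adjusted p = 0.459 for each with an estimated correlation). MHC class II, T and NK cell, B cell and ribosomal lists had negative differences (limma camera, adjusted p = 0.000442, 0.000314, 0.00631 and 0.00309, and adjusted p = 0.459, 0.562, 0.778 and 0.83 with an estimated correlation). Without 6 libraries with transcripts of other tissues, a choice made after seeing the data, 1 control library per depot was left and assumed to vary like the other groups. In that fit the T and NK cell and B cell lists pointed up (limma camera, adjusted p = 0.0185 and 0.0189) and the oxidative phosphorylation list down (adjusted p = 2.53e-08). MHC class II, epithelial and ribosomal lists turned without a call (limma camera, adjusted p = 0.242 to 0.675), and matrix and TGF-beta lists lost theirs (adjusted p = 0.0725 and 0.113). Smooth muscle, skeletal muscle, epithelial and oxidative phosphorylation lists had positive differences (limma camera, adjusted p = 0.000374, 4.24e-05, 0.0325 and 0.00973, and adjusted p = 0.459, 0.459, 0.459 and 0.83 with an estimated correlation).

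The count of 2 genes went to 1 with edgeR on recovered reads, 0 with limma-voom and 692 with DESeq2, and to 6 without the 6 libraries, namely Per3, Hlf, Tef, Arc, Fosl2 and Pcsk6, named after their values were seen. With the replicate block the count was 0. Leaving out 1 library changed the count of 2 in all but 2 of 18 cases. Leaving out eWAT ZT3 control replicate 1, 2 or 3 gave 16, 267 and 0 genes, and ZT3 shiftwork replicate 1, 2 or 3 gave 0, 0 and 7. Leaving out eWAT ZT12 control replicate 1 or 2, or ZT12 shiftwork replicate 1, 2 or 3, gave 1 each. In iWAT, leaving out control replicate 1, 2 or 3 gave 0, 0 and 507 genes, and shiftwork replicate 1 or 2 gave 1 and 3.

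Between eWAT ZT3 and ZT12 the fold changes of 15141 genes correlated at r = 0.0653, and at unadjusted p under 0.01 the higher sets of 387 and 36 genes shared 0 (0.92 if independent), as did the lower sets of 327 and 14 (0.302 if independent), while 5 genes were shared in opposite directions. Between eWAT and iWAT at ZT3 the correlation was r = -0.0165 over 14109 genes, with 3 higher genes shared (3 if independent; Fisher's exact p = 0.581, one-sided) and 1 lower gene shared (0.786 if independent), and 9 shared in opposite directions. Genes are not independent replicates, and these pairs share no library. Without the libraries left out for transcripts of other tissues the correlations were -0.272 and -0.0681. Some libraries kept there held such transcripts too, as did eWAT ZT12 shiftwork replicate 2 (intestine markers, 832 CPM). In that fit eWAT ZT3 and ZT12 shared 8 lower genes (2.16 if independent, Fisher's exact p = 0.0014, one-sided) and 25 in opposite directions, with a single ZT3 control library.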

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

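The tests of other sample splits and of dilution by other tissue were written down before their values were seen. The tests on vas deferens, caput epididymis, shared time of day, the clock score, the clock stage and lymph node tissue were chosen after seeing the results, as was leaving out libraries with transcripts of other tissues.

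The interaction of shiftwork and time in eWAT was set apart because it tests directly whether the time-of-day difference differs between schedules. List medians were 2.21 for the positive arm of the clock, -0.94 for clock repressors and outputs, -0.73 for interferon response, -0.72 for MHC class II, 0.90 for lipogenesis, 1.02 for cholesterol synthesis and 1.23 for immediate early genes. They were 0.33 for TGF-beta, 0.0928 for oxidative phosphorylation, 0.20 for antioxidant, -0.27 for lysosome and 0.20 for ribosomal genes. Among cell types they were 2.37 for mast cells, 2.65 for B and plasma cells, 2.50 for lymphatic endothelium, 4.51 for smooth muscle, 1.36 for mesothelium, 3.61 for epithelium and 1.35 for Schwann cells.

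The difference of the shiftwork effect between iWAT and eWAT was set apart for the same reason, as a direct test between depots. Adamts4 stood at 3.58 and Phlda1 at 2.41, and list medians were 2.56 for the positive arm of the clock, -0.79 for repressors and outputs, 0.84 for matrix, 0.52 for TGF-beta, 1.39 for inflammatory, -1.45 for MHC class II, 0.26 for oxidative phosphorylation and 0.89 for cholesterol synthesis genes. They were 0.36 for endoplasmic reticulum chaperones, 0.66 for heat shock, 1.19 for glucocorticoid-responsive and 1.06 for immediate early genes. Among cell types and ribosomal genes they were -2.25 for T and NK cells, -2.61 for B and plasma cells, 3.66 for smooth muscle, 4.04 for skeletal muscle, 1.28 for epithelium and -0.37 for ribosomal proteins.

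Genes lower at ZT12 in control eWAT could reflect vas deferens tissue in ZT3 control replicates 1 and 3 or a time-of-day difference. Of the 116 lower genes 41.4 percent were more than 2-fold higher in those libraries, each, than in replicate 2, against 9.4 percent of all tested genes, a share between the limits set for and against that cause. Of the 705 lower genes found without replicate 2 it was 73.8 percent, above the limit for it, though replicates 1 and 3 themselves picked those genes. Caput epididymis was excluded as a source, since its markers reached at most 3.42 CPM there. A shared time-of-day difference was left open for the lower genes (42 percent of those found without replicate 2 were higher in it than in all ZT12 control libraries, against 33.1 percent of all genes). For the higher genes it fitted (94 percent against 37.3 percent, though the ZT12 libraries also took part in picking them), and dilution by other tissue was neither shown nor excluded (median 0.111 against 0.00779 for all genes).

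The clock difference between schedules at ZT3 in eWAT could rest on ZT3 control replicate 2, where Arntl was highest, or on other tissue. Without that library the difference of the clock score kept 67.6 percent of its value (-1.13 ± 0.27), so that library alone was excluded as the whole cause. Without the 3 libraries with male tract or germ cell transcripts it was 171 percent (-2.85 ± 0.336), with the spread of the control taken from the other groups. The control left was replicate 2 alone, the library with the highest score (0.719 against -1.21 and -0.608). The rise is thus that library's own value, and the role of those tissues was not settled. A clock that stands at a later stage at ZT3 in shiftwork mice is a possible biological reading. No test separated it from the causes above. From ZT3 to ZT12 the score changed by 0.265 ± 0.445 (SE) in shiftwork mice (two-sided exact permutation p = 0.4). In control mice the change was -1.68 ± 0.445 (two-sided exact permutation p = 0.1). The score thus cannot tell a later stage from a smaller time-of-day difference in shiftwork mice.

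Lower B and T cell transcripts in iWAT of shiftwork mice may come from lymph node tissue in control replicates 1 and 2 or from fewer lymphocytes in shiftwork mice. Of 26 tested B and T cell genes 96.2 percent were more than 4-fold higher in those libraries, each, than in control replicate 3, which fits lymph node tissue. The summed level of lymph node stroma markers was higher there too. That list includes Ltb, which lymphocytes also express, so its sum is not separate evidence. Fewer lymphocytes in shiftwork mice stayed open: 3.85 percent were higher in control replicate 3 than in all shiftwork libraries, a share below the limit set against that cause, but control replicate 3 is a single library and excludes nothing.

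Other splits of the same libraries were fitted for each count of genes. For shiftwork at ZT3 (real 0, highest other 2662), at ZT12 (0 and 0), for time in shiftwork (0 and 0) and for iWAT (0 and 4), all 10 of 10 splits gave at least as many genes, which a count of 0 fixes beforehand, and the splits are also too few for a share under 0.05. For time of day in control 1 of 10 splits, the real one, gave as many (559, highest other 0), and again the splits are too few for a share under 0.05. The split at ZT3 with 2662 genes placed control replicates 1 and 3 with shiftwork replicate 3, which points to a structure of the samples. For the averaged effect and the interaction 100 of 100 splits gave as many (real 0, highest other 947 and 1287), so chance could not be excluded, which a count of 0 fixes beforehand. For the depot difference 35 of 100 splits gave as many (real 2, highest other 1690), so chance could not be excluded. Splits that call many genes point to a structure of the samples.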

How the results depend on the processing

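Zero counts for shiftwork in eWAT (ZT3, ZT12, averaged), for time in shiftwork, for the interaction and for iWAT were kept with RLE, no filter, a mean CPM of at least 1, limma-voom, a replicate block and the deposited FPKM or RPKM. They were not kept with DESeq2, which called 629 genes at ZT3, 7 at ZT12, 42 averaged, 287 for time in shiftwork, 189 for the interaction, 445 in iWAT, 692 for the depot difference and 2168 for time of day in control. Sample quality weights, added after seeing the data and not fully converged, gave 2563 at ZT3, 195 averaged, 285 for time in shiftwork, 2014 for the interaction, 4123 in iWAT, 43 for the depot difference and 5085 for time in control. Without the libraries with transcripts of other tissues, also added after seeing the data, the counts were 9 at ZT3, 4 averaged, 75 for time in shiftwork, 7 for the interaction and 6 for the depot difference. For time of day in control no filter gave 320 against 559, and RLE, a mean CPM of at least 1, limma-voom, the deposited FPKM and a fit of only the 2 groups stayed within 1.5 times. The depot difference of 2 went to 1 with RLE, with edgeR TMM on recovered reads and without a filter, and to 0 with limma-voom. The cause was not tested, except that leaving out libraries leaves fewer samples. Some libraries kept in the fits without libraries with transcripts of other tissues held such transcripts too.

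With 1 library left out, counts ran from 0 to 403 at ZT3, 0 to 88 averaged, 1 to 2744 for time in control, 0 to 186 for the interaction, 0 to 827 in iWAT and 0 to 507 for the depot difference, and the correlations from -0.394 to 0.259 (eWAT ZT3 and ZT12) and -0.0496 to 0.132 (eWAT and iWAT). All 52 named genes called for time in control lost the call in some such fit, and 0 changed sign.

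A replicate block gave 298 genes for time of day in control and 0 for the depot difference, and of the eWAT libraries 2 of 12 correlated best with their own number, so the numbers were not read as pairs outside ZT12. At ZT12 the block called 0 genes, as without it, and 1 further list, T and NK cells (camera of limma, adjusted p = 0.0293 against 0.122).

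With an estimated correlation 0 lists were called in any of the 8 comparisons, and fry called 0 in 6 of them, 6 for time in control and 2 for the depot difference. Without the libraries with transcripts of other tissues 12 lists, against 19, were called for the interaction, the ZT3 and ZT12 correlation was -0.272 against 0.0653, and that of eWAT and iWAT -0.0681 against -0.0165. At unadjusted p under 0.01 eWAT and iWAT shared 4 genes in the same direction, against 0 at the adjusted threshold. In those fits for time in control Hlf was 1.16 (adjusted p = 0.0295, edgeR), Des 0.31 (adjusted p = 0.213) and Tagln 0.055 (adjusted p = 0.943), each with the sign reversed. In that fit 1 ZT3 control library was then left and was assumed to vary like the others. Over settings, 1508 values of the 98 genes named for time in control kept sign and call, and 506 lost and 117 gained the call. The sign reversed in 3 values called in at least 1 of the fits, and in a further 14 called in neither. Depth leaves genes under about 0.147 CPM unresolved in eWAT, and folds of 1.5 were recovered in at most 14 percent of simulated genes.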

Other observations

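Adipocyte identity genes, insulin and glucose genes and thermogenic genes had medians of 0.18, 0.12 and -0.13 for shiftwork in eWAT at ZT3 (camera of limma, adjusted p = 0.975, 0.904 and 0.122) and of 0.02, 0.05 and -0.10 in iWAT (adjusted p = 0.61, 0.999 and 0.999). For insulin and glucose genes the camera direction at ZT3 in eWAT was down while the median was above 0, and for thermogenic genes in iWAT it was up while the median was below 0. The mean of the thermogenic list at ZT12 was 0.36 and its median 0.06 (adjusted p = 0.796). Without the libraries with transcripts of other tissues, which leaves 1 control library per depot, the thermogenic list pointed down at ZT3 in eWAT (adjusted p = 0.000313), and in iWAT so did thermogenic, adipocyte and insulin lists (adjusted p = 2.75e-05, 6.15e-05 and 0.000887). Nuclear-retained RNA had medians of -0.22 in eWAT at ZT3 and -0.42 in iWAT (camera of limma, adjusted p = 0.314 and 0.235). Mitochondrially encoded genes, tested in iWAT, had a median of -0.14 (camera of limma, adjusted p = 0.61). Epididymis and testis genes in eWAT at ZT3 had a median of 6.49 with the camera direction down (limma, adjusted p = 0.838), and in the depot difference a median of -2.72 (adjusted p = 0.971).

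Hepatocyte markers summed to 319 CPM in eWAT ZT12 shiftwork replicate 2, with 5 of 14 above 1 CPM. That library also held intestine markers (832 CPM), and whether the hepatocyte markers came from liver was not tested. They summed to 103 and 163 CPM in iWAT shiftwork replicates 1 and 3, with 14 of 14 above 1 CPM. In iWAT control replicate 3 the sum was 104 CPM with 2 of 14 above 1 CPM. Markers of lymph node stroma summed to 89.6 CPM in iWAT shiftwork replicate 3. eWAT ZT3 shiftwork replicate 3 had the most genes with a read (19778) and the smallest share of reads in its 10 most abundant genes (6.22 percent).

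Because positive-arm clock genes stood lower in eWAT and higher in iWAT of shiftwork mice at ZT3, a shifted clock stage in iWAT was put forward as a hypothesis and tested after seeing the results. If so, the iWAT shiftwork effects of clock genes would run against the ZT12 to ZT3 difference of control eWAT, with which they share no library. Across 19 clock genes the correlation was r = -0.546 (rho -0.374), which lay inside the central 95 percent of random gene lists of that size (-0.611 to 0.808). The negative sign restates what prompted the hypothesis. Positive-arm genes were higher in shiftwork iWAT and lower at ZT12 in control eWAT, so the sign is no evidence of an earlier stage. In iWAT the clock score differed between schedules by 0.805 ± 0.442 (two-sided exact permutation p = 0.2). The difference had the same sign in eWAT at ZT12 (0.274 ± 0.445). The control score was -2.37 ± 0.478 (SD) in iWAT, against -0.366 ± 0.986 at ZT3 and -2.05 ± 0.0767 at ZT12 in eWAT. Depot and table differ between these scores, so they do not settle the sampling time of iWAT. If the recurring sample numbers mark animals, the time of 1 of the tissues is also in doubt. Chance was not excluded, and genes are not independent replicates.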
